A study of Caenorhabditis elegans with 2 samples.

How the data were processed

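The study measured binding of 1 tagged protein in whole young adult worms by chromatin immunoprecipitation with an antibody against GFP, per the labels. The labels give 2 biological replicates of the same strain, collected at 66 hours, and no other group, so both samples form 1 group and no test between groups was possible. Fragments of 200 to 800 bp came from sonication, per the labels. The labels also list an experiment as a possible control, which is not analysed here.

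The data used are peak lists. Per the file headers and accompanying notes, the authors made a thresholded and a ranked list from the alignment of each sample, and a larger and a conservative pair of lists from the alignments of both samples. Each derives as well from 1 file shared by both samples whose type is not stated, and the thresholded lists from 1 more file. The assembly is ce11, per the file headers and the labels. The aligner, the peak caller and their versions are not given in the sources used here. The signal value of a peak was deposited by the authors as their caller wrote it, and no scaling between samples is stated, so it is used here only to describe, rank or filter peaks. The deposited lists also carry a −log10 q value, which decides no result here. The deposited score is a scaled irreproducible discovery rate (IDR), the estimated rate at which a peak fails to recur, with 1000 as its highest value. The ranked lists carry the IDR itself, as a −log10 value deposited by the authors, and thresholded peaks had an IDR of at most 0.01 in the values. The ranked lists hold 4 unnamed columns of values per run, which were not used. Peak lists carry no read counts, so depth is unknown and precision is set by the number of peaks or genes. Wilson 95% intervals are given on shares and cover counting error only.

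For named sites, the signal in each replicate is that of the overlapping peak in its ranked list, and the mean and SD are over 2 replicates. Where several peaks of a replicate overlap the interval the highest is taken, so with several summits in 1 interval the value can belong to another of them. Of 99 named genes 9 had such an interval, and only rpn-3 took a value from a neighbouring summit, 175 in replicate 1 against 145 at the nearest. Annotation was Ensembl release 115 on WBcel235, the same assembly as ce11, with gene names from that annotation. Of the protein-coding genes, 205 share a name with a copy and were kept apart by gene identifier. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.

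The tests, the gene lists and the rule for named items were fixed before the data were examined. Replicate overlap counted peaks sharing at least 1 bp and was set against 1000 circular shifts of the other sample's peaks along each chromosome (smallest shift 5000 bp, seed 11). Overlap with the ranked lists and the alternatives of the overlap used 100 shifts. Summits were assigned, in this order, to promoters (1000 bp upstream to 200 bp downstream of a protein-coding transcript start), 5' UTRs, coding exons, 3' UTRs, introns, noncoding genes and other intergenic space, and compared with 1000 shifts of the summits, two-sided. Distances to the nearest start and noncoding genes within 500 bp of a summit were treated likewise. Benjamini-Hochberg adjustment ran over 7 position classes, 8 noncoding classes, 2 chromosome tests, 34 gene lists and 2080 6-mers. Gene lists and chromosomes were compared by Fisher's exact test, two-sided, over 19973 protein-coding genes, with 0.5 added to each count of an odds ratio. An adjusted p below 0.05 passed. Genes, peaks and summits are not independent replicates, so these p-values describe the peak set and not a population of worms.

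The lists took members by name prefix or from fixed symbols. Prefix lists covered cytosolic and mitochondrial ribosomal proteins, translation factors, aminoacyl-tRNA synthetases, proteasome subunits, vitellogenins, major sperm proteins, histones, C-type lectins, nuclear hormone receptors, chemoreceptors, F-box genes, cytochrome P450 genes, glutathione S-transferases with UDP-glucuronosyltransferases, neuropeptide and insulin-like genes, and pre-mRNA splicing. Fixed symbols, in part with prefixes, covered folding and unfolded protein response in the endoplasmic reticulum, cytosolic chaperones, mitochondrial chaperones and proteases, the respiratory chain, cuticle collagens, homeobox genes, small RNA pathways, germline and oocyte genes, sperm genes, markers of intestine, body wall muscle, pharynx, neurons and hypodermis, the cell cycle, the vacuolar ATPase with lysosome and autophagy, chromatin regulators, and RNA polymerase II transcription.

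Words were counted as present or absent within 50 bp of each summit (101 bp) and in a window of the same size centred 200 bp away, with an exact sign test over the peaks in which they differ. The plan named windows on each side. The side was drawn at random for each peak, because a sign test of 1 window against a pair would be unbalanced, and runs with the control on a fixed side were added afterwards.

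Named items are the 25 protein-coding genes with the highest promoter signal, up to 4 bound members with the highest signal of each list that passed, the 10 strongest peaks, the tagged gene and the 10 6-mers with the smallest p. Other items are said to be chosen after their values were seen.

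The steps of replicate overlap, position of peaks, gene lists and sequence at summits were tested on simulated data. Signal correlation, summit distances, chromosome tests, noncoding classes, circular shifts for the lists and the logistic model were not. With 60% of 3291 peaks planted as shared, the replicate overlap step gave 61.2%, and shifts gave 2.81%. For the position of peaks, 0 of 7 classes passed for random peaks, and a planted excess at starts gave a promoter share of 63.2% over 3291 peaks with an adjusted permutation p of 0.0139. Over 19973 genes, the list test called 7 of 10 planted lists of 20 genes bound at 40%, and 0 of 24 unchanged lists. In the sequence step, 0 of 2080 6-mers passed in random windows, and a planted word ranked 1 with an adjusted p of 4.6e-31.

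Alternatives, whose effect the closing part gives, were the larger set, the 50% of peaks with the highest signal, each replicate's own peaks, other promoter windows (500 bp to 100 bp and 2000 bp to 500 bp), assignment to the nearest start, gene backgrounds without possible operon genes or with xxx-n names alone, circular shifts for the lists, other distances for noncoding genes, other windows and controls for words, and other rules of overlap. Restriction to an IDR score of 1000, and to a signal of at least 50 with 1 summit per interval, was added after seeing the data, as were the fixed-side controls.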

Results

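Chromatin immunoprecipitation followed by sequencing was used to ask where a tagged protein sits on the genome of the nematode Caenorhabditis elegans. The worms, strain RW12180, carried a TY1, EGFP and 3xFLAG tag that CRISPR had placed on a chromosome I gene, which the labels call dox-1 and, as the CRISPR target, dxbp-1. Whole young adults were collected at 66 hours, after synchronisation by bleaching and starvation of hatched larvae. Their chromatin was sonicated to 200 to 800 bp, and an antibody against GFP pulled down the fusion protein. There were 2 biological replicates in 1 group and no second condition, so the data describe where the protein was found and not how that changed. The peak lists carry no read counts, so the depth of each sample is unknown. Coordinates are 1-based on build ce11 (WBcel235).

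The authors deposited peak sets called from each sample and sets called from both samples, each peak with a summit and a signal value of their own. The conservative set from both samples held 3291 peaks, with a median signal of 255.6 and a range of 2.01 to 2754.3. The larger set from both samples held 4441 peaks. Replicate 1 alone gave 3105 peaks with a median signal of 140.2, and replicate 2 alone gave 2983 with a median of 144. The ranked lists behind them, before any threshold on reproducibility, held 56265 peaks in replicate 1 and 65301 in replicate 2. In the conservative set, 83 peaks had a signal below 50, and the 3291 summits lay in 3223 distinct intervals with a median width of 436 bp. Results below rest on this conservative set unless another is named.

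The strongest sites had high signal in both replicates, which their choice by signal from a set kept for reproducibility between the samples favours. Upstream of rpl-3, which encodes a protein of the large ribosomal subunit, signal was 1512 in replicate 1 and 1250 in replicate 2. The site shared by rpl-15, another ribosomal protein gene, and K11H12.8 had 1375 and 1241. At mog-4, which encodes an RNA helicase of the switch from sperm to oocytes, the values were 1132 and 1114. Upstream of rpl-20 and of cdc-48.1, which encodes an ATPase that extracts ubiquitinated proteins, replicate 2 was higher, at 974 against 821 and at 978 against 742.

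Across the whole sets, 1995 of the 3105 peaks of replicate 1 (64.3%, Wilson 95% interval 62.5 to 65.9) overlapped a peak of replicate 2 by at least 1 bp. Of the 2983 peaks of replicate 2, 2059 did so (69.0%, interval 67.3 to 70.7). After circular shifts of the other sample's peaks along each chromosome, the means were 2.104% and 2.21%, and the highest of 1000 shifts gave 3.19% and 3.29%. The one-sided permutation p was 0.001 in both directions, the smallest that 1000 shifts can give. Many peaks missing from the other thresholded set were present lower in its ranked list: 97.4% of the peaks of replicate 1 and 86.6% of those of replicate 2 overlapped a ranked peak of the other sample, against 34.6% and 31.4% under shifts (permutation p = 0.0099, the smallest that 100 shifts can give).

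Over the 1851 pairs of overlapping peaks, Pearson's r of log2 signal was 0.87 and Spearman's rho was 0.788. The median log2 ratio of replicate 1 to replicate 2 was 0.10 with an SD of 0.35 across pairs, and 99.2% of pairs lay within 2-fold. These correlations run across peaks within 1 pair of samples, and peaks are not independent replicates. Over all ranked peaks that overlapped, rho was 0.586 and 76.5% of pairs lay within 2-fold.

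**Figure D1:**
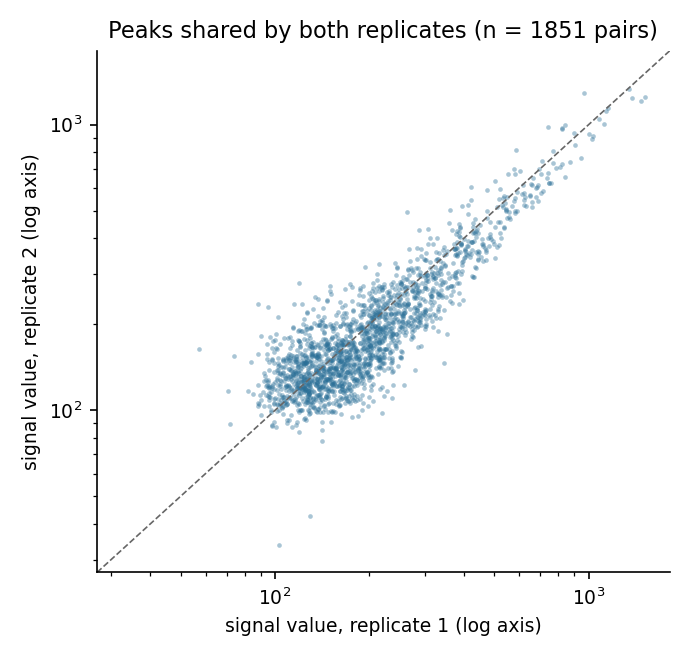
Signal value in replicate 1 (x, log axis) against replicate 2 (y, log axis) for the 1851 pairs of overlapping peaks, 1 point per pair, with the dashed line at equal signal. Points lie along the line (Spearman's rho 0.788), with more scatter at low signal.

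Of the 10 strongest peaks, 6 lay at promoters, and 3 of these were promoters of ribosomal protein genes. The highest peak lay at III:3867336-3867795, with its summit at -272 bp from the start of rpl-3 (III:3867854-3869587, plus strand), and the mean of the replicates was 1381 ± 186 (SD, n = 2). A peak at III:10759023-10759525 was shared by the divergent promoters of tasp-1, which encodes a threonine aspartase, and K01G5.10, at 1342 ± 185 (SD, n = 2). The peak between rpl-15 and K11H12.8 on chromosome IV had 1308 ± 94.6 (SD, n = 2). The promoters of mog-4 at 1123 ± 12.7 (SD, n = 2) and rpl-35 at 1063 ± 79.7 (SD, n = 2) followed. Signal at rpa-2, which encodes a subunit of the single-stranded DNA binding protein of replication, was 965 ± 55.1 (SD, n = 2).

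The remaining genes among the 25 with the highest promoter signal include several with known roles. The divergent pair set-16, a histone methyltransferase gene, and drr-2, which encodes a translation initiation factor homologue, had 972 ± 87.1 (SD, n = 2). The pair rpl-20 and Y17G9B.5 had 898 ± 108 (SD, n = 2), and mtcu-2, a homologue of genes for mitochondrial tRNA modification, had 958 ± 94.0 (SD, n = 2). The promoter of cdc-48.1 had 860.0 ± 167 (SD, n = 2). F44E5.4 and F44E5.5, neighbouring heat-inducible chaperone genes, shared a peak with 854 ± 126 (SD, n = 2). The cytochrome c oxidase genes cox-5A and cox-5B had 773 ± 67.8 (SD, n = 2) and 711 ± 44.5 (SD, n = 2). The pair wip-1 and larp-1, the latter encoding an RNA-binding protein, had 761 ± 72.6 (SD, n = 2), and cnk-1, a scaffold gene of Ras signalling, had 746 ± 59.97 (SD, n = 2). The pair sec-61.G, a subunit gene of the channel for secreted proteins, and F32D8.13 had 697 ± 6.46 (SD, n = 2). H41C03.3 and K12H4.5 completed these genes, at 749 ± 134 (SD, n = 2) and 728 ± 28.2 (SD, n = 2). The peak assigned to H41C03.3 had its summit at -971 bp from its start and 59 bp from sls-2.1, a gene of spliced leader RNA.

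Not all of the 10 strongest peaks were at promoters: 4 lay between genes on chromosome IV. The second strongest peak of all, at IV:4727829-4728259, had 1339 ± 2.18 (SD, n = 2). Its summit was 2902 bp downstream of the nearest protein-coding start, that of K08F11.1, and 85 bp from a pseudogene. A further peak, at IV:4725399-4725814, had 1063 ± 27 (SD, n = 2), with its summit 452 bp downstream of the same start and 144 bp from an ncRNA gene. The peaks at IV:9196213-9196629 and IV:15059086-15059564 had 1146 ± 7.11 (SD, n = 2) and 1128 ± 227 (SD, n = 2). Their summits lay 847 bp downstream of the start of C46C2.7 and 1041 bp downstream of that of Y41E3.13, the nearest protein-coding starts. They were 374 bp and 126 bp from ncRNA genes. Of the 100 strongest summits, 63 were in promoters, 24 between genes, 10 in introns, 2 in noncoding genes and 1 in a coding exon.

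The question of where in the genome the protein was found was then put to all summits. Promoters, here from 1000 bp upstream to 200 bp downstream of a protein-coding transcript start, held 1820 of the 3291 summits (55.3%, Wilson 95% interval 53.6 to 57.0). Circular shifts of the summits put 25.9% there on average and 28.7% at most, so promoters held 2.14 times the shifted share. Coding exons held 4.80% against 18.9% after shifts, introns 16.3% against 27.6%, and 3' UTRs 1.09% against 2.37%. Noncoding genes held more than after shifts, at 4.56% against 3.29%, and the rest of the intergenic space held less, at 17.5% against 21.6%. Each of these 6 classes had a two-sided permutation p of 0.002, the smallest that 1000 shifts can give, and 0.00233 after adjustment over 7 classes. The share in 5' UTRs outside promoters, 0.365% against 0.417%, did not pass (adjusted permutation p = 0.779).

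**Figure D2:**
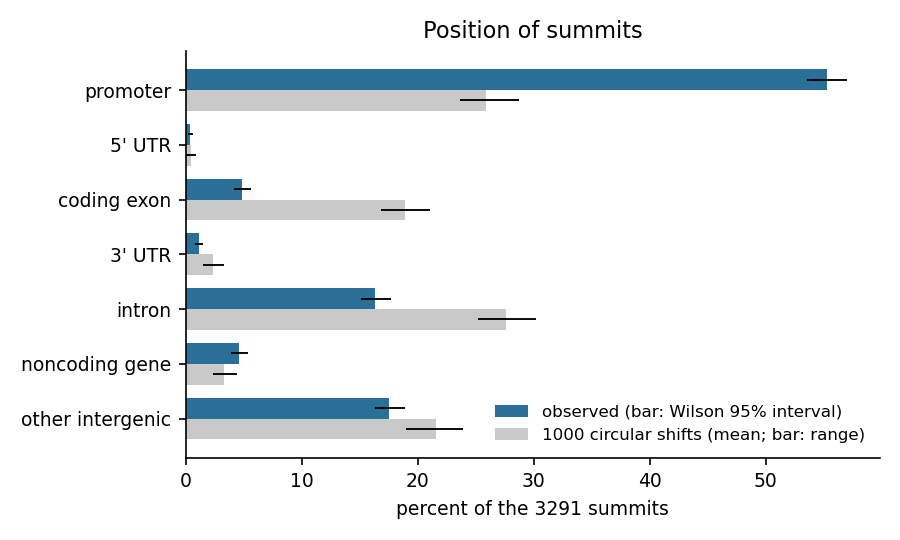
Percent of the 3291 summits (x) in each annotation class (y), observed (blue, with Wilson 95% intervals) and as the mean of 1000 circular shifts (grey, with their range). Promoters held 55.3% of summits against 25.9% after shifts, and coding exons 4.80% against 18.9%.

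Stronger peaks were more often at promoters. With the peaks split into 4 groups of equal size by signal, the promoter share was 46.9%, 50.4%, 57.8% and 66.1% from the weakest to the strongest group (Fisher's exact test of strongest against weakest, two-sided, p = 4.8e-15). Over the same groups, coding exons held 11.5%, 5.10%, 1.95% and 0.608%.

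Summits lay nearer to annotated starts than shifted summits did, and more often upstream than downstream of them. The median summit lay at -169 bp relative to the nearest protein-coding start (interquartile range -694 to 302 bp), while the shifted summits had a mean median of 252 bp. The median absolute distance was 536 bp against 1329 bp, and 48.6% of summits lay within 500 bp of a start against 22.8% after shifts. Both medians differed from the shifts with a two-sided permutation p of 0.002, the smallest possible. In total 67.9% of summits were upstream of their nearest start. At xbp-1, which encodes a transcription factor of the unfolded protein response, the summit was at -5 bp, and at the ribosomal gene rpl-35 it was at -443 bp.

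Bound genes were most frequent on chromosomes III and I and least frequent on V. A protein-coding gene was counted as bound when a summit lay in the promoter window of any of its transcripts, which was so for 2183 of 19973 genes (10.9%). By chromosome the share was 15.4% on III, 14.8% on I, 11.2% on IV, 10.4% on II, 9.81% on X and 7.19% on V. Genes in the central 50% of each autosome, where essential genes concentrate, were bound in 12.3% of cases (1176 of 9596), against 9.67% (739 of 7646) in the outer parts. The odds ratio was 1.31 (Fisher's exact test, two-sided, adjusted p = 1.4e-07). On X, 268 of 2731 genes were bound against 1915 of 17242 on the autosomes (11.1%), an odds ratio of 0.872 with p = 0.0441 by Fisher's exact test, adjusted over both chromosome tests. That difference ended with the larger set from both samples, where the odds ratio was 0.946 (Fisher's exact test, p = 0.369). Genes are not independent replicates, and 567 of the 1820 promoter summits (31.2%) lay in windows of 2 or more genes.

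Gene groups of protein synthesis were among the most often bound, where bound means a promoter summit. The possible control experiment was not analysed, so whether these summits depend on the tagged protein was not tested for any list. Of 81 cytosolic ribosomal protein genes, 55 had a promoter summit (67.9%, Wilson 95% interval 57.1 to 77.1), against 10.7% of all other protein-coding genes. The bound genes include 29 with the prefix rpl, of the large subunit, among them rpl-3, rpl-15, rpl-35 and rpl-20, given above, and 25 with the prefix rps, of the small subunit. The median of the strongest summit per bound gene was 388 against 295 for all bound genes. Translation factors were bound at 17 of 37 genes (45.9%). Of these, eif-3.C, a subunit gene of an initiation factor, had 470 ± 74.96 (SD, n = 2). The elongation factor genes eef-1G and eef-1A.1 had 397 ± 14.5 (SD, n = 2) and 299 ± 1.5 (SD, n = 2), and eif-2Bgamma, an exchange factor subunit gene, had 364 ± 45.5 (SD, n = 2) at a summit inside the snRNA gene sup-39. The odds ratios were 17.5 for ribosomal proteins (Fisher's exact test, two-sided, adjusted over 34 lists, p = 7.8e-33) and 7.002 for translation factors (adjusted p = 3.0e-07).

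Other groups of protein synthesis had smaller odds ratios. Mitochondrial ribosomal proteins were bound at 16 of 70 genes (22.9%), with mrpl-15 at 314 ± 61.3 (SD, n = 2), mrpl-12 at 229.6 ± 35.1 (SD, n = 2), mrpl-28 at 217 ± 11.5 (SD, n = 2) and mrps-7 at 217 ± 1.60 (SD, n = 2). Aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, were bound at 8 of 31 genes (25.8%), with ears-2 at 399 ± 56.3 (SD, n = 2), aars-1 at 207 ± 2.78 (SD, n = 2), yars-2 at 159 ± 17.8 (SD, n = 2) and pars-1 at 125 ± 44.0 (SD, n = 2). The odds ratios were 2.48 (adjusted p = 0.00612) and 2.95 (adjusted p = 0.0270) by Fisher's exact test. Neither call held with circular shifts in place of that test (adjusted permutation p = 0.0894 and 0.235). Without replicate 2 the mitochondrial list had an adjusted p of 0.100 by Fisher's exact test, and the synthetases had 0.321 without replicate 1 and 0.163 without replicate 2.

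Groups of protein folding and turnover had larger shares of bound genes. Of 22 genes of the unfolded protein response and folding in the endoplasmic reticulum, 13 were bound (59.1%). They include hsp-3, which encodes a resident chaperone of that compartment, at 445 ± 55.3 (SD, n = 2), the chaperone gene enpl-1 at 380.2 ± 43.3 (SD, n = 2), and the stress regulators atf-6 and xbp-1 at 275 ± 58.1 (SD, n = 2) and 263 ± 51.8 (SD, n = 2). Of 18 cytosolic chaperone and heat shock genes 9 were bound (50%), among them F44E5.4 and F44E5.5, the co-chaperone gene dnj-13 at 429 ± 73.5 (SD, n = 2), and hsp-1, a constitutive chaperone gene, at 383 ± 27.8 (SD, n = 2). Proteasome subunits were bound at 15 of 33 genes (45.5%), with rpn-11, whose product removes ubiquitin, at 265 ± 22.3 (SD, n = 2), rpn-2 at 242 ± 33.4 (SD, n = 2), rpn-9 at 229 ± 13.1 (SD, n = 2) and rpn-3 at 223 ± 67.0 (SD, n = 2). Genes of the vacuolar ATPase, lysosome and autophagy were bound at 21 of 50 (42%). In that list vha-18 shared a peak with pos-1 at 270.3 ± 78.6 (SD, n = 2), vha-13 had 252 ± 34.9 (SD, n = 2), the autophagy gene epg-7 had 249.9 ± 75.5 (SD, n = 2), and hlh-30, a regulator of lysosomal genes, had 242 ± 50.3 (SD, n = 2). By Fisher's exact test the odds ratios were 11.6 (adjusted p = 2.5e-07), 8.18 (adjusted p = 9.6e-05), 6.87 (adjusted p = 1.7e-06) and 5.99 (adjusted p = 8.5e-08), in the order given.

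The respiratory chain and ATP synthase list was bound at 20 of 38 genes (52.6%). Besides cox-5A and cox-5B, atp-1, the alpha subunit gene of the synthase, had 539 ± 60.3 (SD, n = 2), and cox-6B had 449 ± 3.51 (SD, n = 2). The odds ratio was 9.10 (Fisher's exact test, adjusted p = 2.2e-09).

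Genes of RNA processing and chromatin formed a further set of bound groups. Pre-mRNA splicing genes were bound at 21 of 38 (55.3%), with prp-19 at 637 ± 33.5 (SD, n = 2), the Sm protein gene snr-4 at 443 ± 96.8 (SD, n = 2) with a summit 26 bp from an snRNA gene, and the divergent SR protein genes rsp-1 and rsp-2 at 359 ± 19.2 (SD, n = 2). Of 27 chromatin regulators 15 were bound (55.6%). Its members with the highest signal were lin-9 at 586 ± 102 (SD, n = 2), lin-54 at 557 ± 26.5 (SD, n = 2) with a summit at -6 bp from the start of rpl-12 and -387 bp from that of lin-54, lin-53 at 513 ± 66.4 (SD, n = 2) with the start of nra-2 nearer to its summit, and lin-35, the retinoblastoma homologue, at 329 ± 51.5 (SD, n = 2). Histones were bound at 24 of 72 genes (33.3%), with his-67 and his-68 sharing a peak at 639 ± 57.0 (SD, n = 2), his-37 at 544 ± 35.4 (SD, n = 2) and his-59 at 282 ± 51.5 (SD, n = 2). The odds ratios were 10.1 (adjusted p = 3.0e-10), 10.2 (adjusted p = 8.5e-08) and 4.15 (adjusted p = 1.1e-06) by Fisher's exact test. In a logistic model with promoter GC content and window length, the histone odds ratio went from 4.11 to 1.82 (95% interval 1.08 to 3.06). Genes of RNA polymerase II transcription were bound at 11 of 38 (28.9%), with the initiation factor genes taf-4 at 335 ± 0.206 (SD, n = 2) and taf-12 at 241 ± 39.6 (SD, n = 2), and the polymerase genes rpb-12 at 268 ± 72.1 (SD, n = 2) and rpb-11 at 252 ± 8.56 (SD, n = 2). Their odds ratio was 3.42 (Fisher's exact test, adjusted p = 0.00358), a call that did not hold with circular shifts (adjusted permutation p = 0.109).

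Cell cycle and germline groups were bound more often as well. Of 25 genes of the cell cycle and DNA replication 12 were bound (48%). They include pcn-1, the sliding clamp gene, at 551 ± 18.8 (SD, n = 2), the helicase gene mcm-4 at 255.2 ± 39.4 (SD, n = 2), and the mitotic kinase genes plk-1 and bub-1 at 196 ± 17.3 (SD, n = 2) and 169 ± 42.3 (SD, n = 2). Germline and oocyte genes were bound at 14 of 33 (42.4%), with pos-1, which encodes an embryonic RNA-binding protein, at 270.3 ± 78.6 (SD, n = 2), the RNA-binding protein gene puf-11 at 237 ± 45.3 (SD, n = 2), the yolk receptor gene rme-2 at 222 ± 21.9 (SD, n = 2) and the oocyte surface protein gene egg-1 at 221 ± 31.4 (SD, n = 2). The odds ratios were 7.58 and 6.09, each with an adjusted p of 9.8e-06 by Fisher's exact test. Small RNA pathway and germ granule genes were bound at 8 of 34 (23.5%), with mut-15 at 247 ± 29.8 (SD, n = 2), the RNA polymerase gene ego-1 at 188 ± 1.24 (SD, n = 2), the Argonaute gene hrde-1 at 170.1 ± 7.07 (SD, n = 2) and rde-12 at 156 ± 51.3 (SD, n = 2). Their odds ratio was 2.62 (Fisher's exact test, adjusted p = 0.0441). That call did not hold with circular shifts (adjusted permutation p = 0.235), nor without replicate 2 (adjusted p = 0.106), and with promoter GC content in a logistic model the odds ratio was 1.83 (95% interval 0.791 to 4.21).

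In 5 lists a smaller share of genes was bound. Chemoreceptor genes, which encode receptors of sensory neurons, were bound at 11 of 1308 (0.841%), with an odds ratio of 0.0673 (Fisher's exact test, adjusted p = 4.5e-50). The bound members include sri-5 at 397 ± 91.2 (SD, n = 2), srh-16 at 248 ± 22.6 (SD, n = 2), srz-97, which shared its peak with the lectin gene clec-57, at 231 ± 60.2 (SD, n = 2), and sre-1 at 189 ± 48.8 (SD, n = 2). F-box genes, of substrate receptors for ubiquitin ligases, were bound at 7 of 322 (2.17%, odds ratio 0.191, adjusted p = 2.7e-08 by Fisher's exact test). Among them were fbxa-83 at 574 ± 79.6 (SD, n = 2), whose summit also lay 37 bp from the snoRNA gene Y67A10A.14, fbxb-58 at 518 ± 58.0 (SD, n = 2), fbxa-90 at 206 ± 36.6 (SD, n = 2) and fbxc-23 at 136 ± 14.8 (SD, n = 2). Neuropeptide and insulin-like genes were bound at 2 of 140 (1.43%), ins-39 at 471 ± 2.71 (SD, n = 2) and nlp-25 at 84.3 ± 5.11 (SD, n = 2), and their odds ratio was 0.146 (Fisher's exact test, adjusted p = 7.1e-05).

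The other lists with a smaller share were less stable. C-type lectins were bound at 10 of 240 genes (4.17%, odds ratio 0.368, adjusted p = 0.000511 by Fisher's exact test), with clec-126 at 240.4 ± 13.2 (SD, n = 2), clec-104 at 203 ± 17.6 (SD, n = 2) and clec-140 at 141 ± 26.2 (SD, n = 2). Cuticle collagens were bound at 6 of 172 (3.49%, odds ratio 0.316, adjusted p = 0.00155 by Fisher's exact test), with col-63 at 370.4 ± 19.3 (SD, n = 2), col-71 at 259.9 ± 31.4 (SD, n = 2), col-52 at 244 ± 40.9 (SD, n = 2) and col-185 at 217 ± 4.21 (SD, n = 2). With circular shifts neither call held (adjusted permutation p = 0.168 for lectins and 0.0717 for collagens). The summits of clec-126 and col-185 lay inside tRNA genes, and the summit shared by clec-57 and srz-97 lay inside the snRNA gene F08H9.11. The collagen odds ratio turned to 1.12 (Fisher's exact test, adjusted p = 0.757) when each summit went only to the nearest start within 1000 bp.

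Many named summits were shared between genes. Of the 82 members named for the 21 lists that passed, 44 shared their summit with another gene, and for 21 of them the start of the other gene was nearer, such as that of fib-1 for mut-15, hsp-110 for rpn-3 and efl-1 for fbxa-90.

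For 13 lists the share bound did not pass the test over 34 lists. Major sperm proteins had 0 of 31 bound (Fisher's exact test, adjusted p = 0.0642). Hypodermis genes had 0 of 14 (Fisher's exact test, adjusted p = 0.456). With circular shifts both had an adjusted permutation p of 0.00523, from the smallest permutation p that 1000 shifts can give, 0.002. That permutation test cannot decide for lists with 0 bound members. Shifted summits reach fewer promoters, so with 0.5 added to counts even a shift with 0 bound members gives an odds ratio above the observed one. Of the tissue marker lists, 2 of 17 intestine genes (exact test, adjusted p = 0.708), 4 of 26 body wall muscle genes (0.591), 2 of 13 pharynx genes (0.665), 2 of 31 neuron genes and 2 of 31 sperm genes (0.609 each) were bound. Vitellogenins had 2 of 6 (0.174), and mitochondrial chaperones and proteases had 3 of 10 (0.123). Nuclear hormone receptors had 19 of 269 (0.0599), homeobox genes 5 of 81 (0.256), cytochrome P450 genes 4 of 74 (0.236), and glutathione S-transferases with UDP-glucuronosyltransferases 7 of 111 (0.174). These p-values are from Fisher's exact test and adjusted over the 34 lists. With 1 replicate's own peaks some passed the same exact test: without replicate 1, nuclear hormone receptors (adjusted p = 0.0408), homeobox genes (0.0267) and cytochrome P450 genes (0.0477), and without replicate 2, nuclear hormone receptors (0.0295), cytochrome P450 genes (0.0108), the transferases (0.0280) and mitochondrial chaperones (0.0231).

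**Figure D3:**
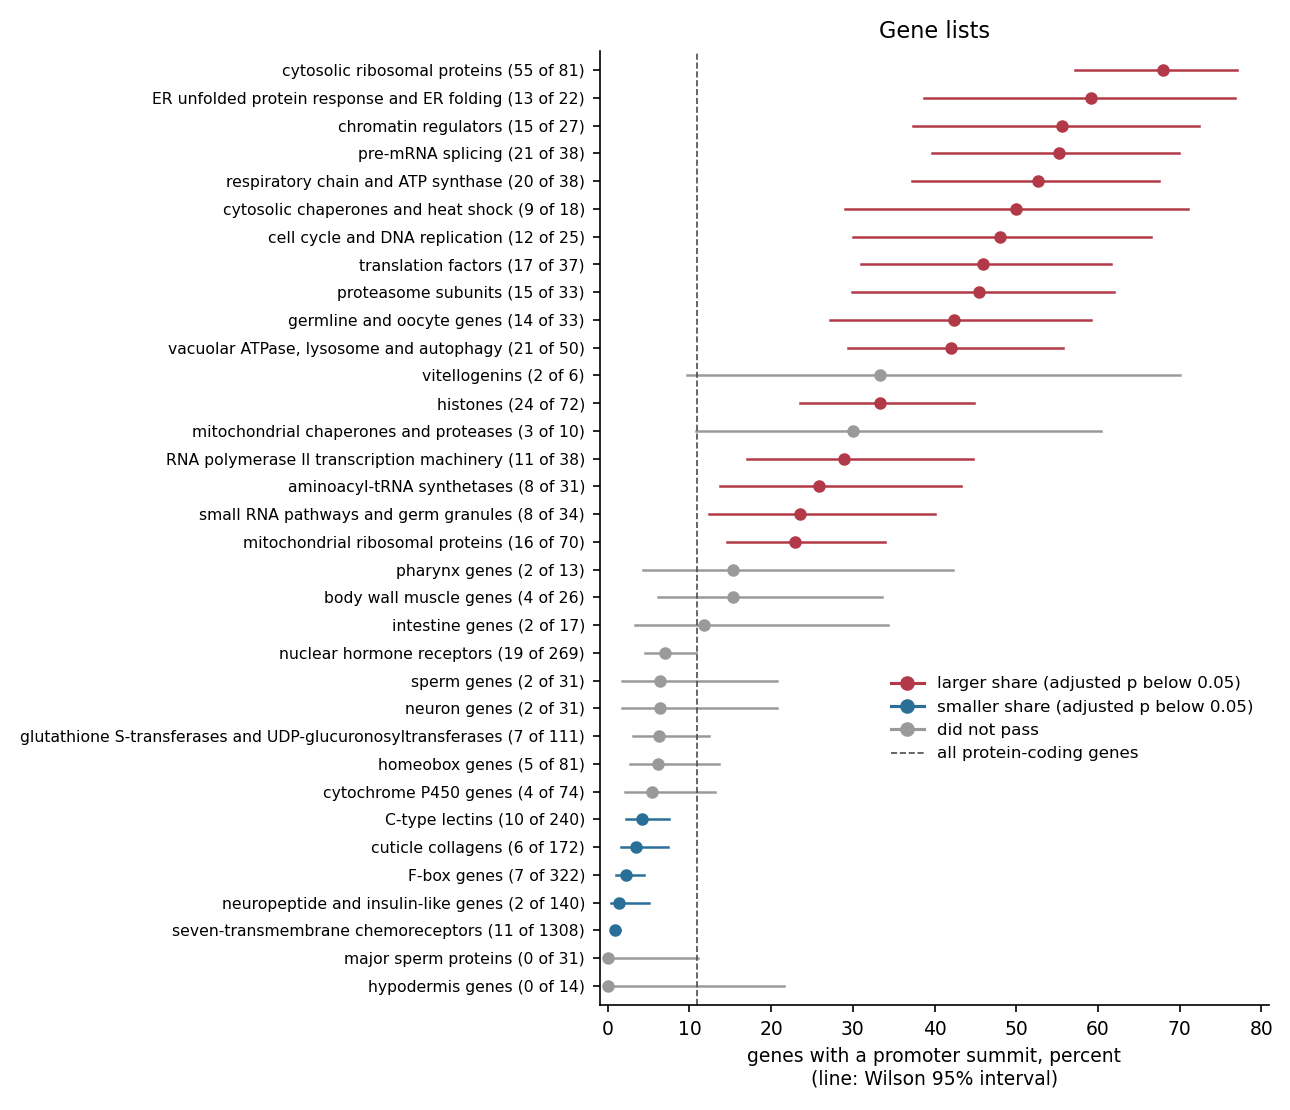
Percent of the members of each of 34 gene lists with a promoter summit (x), with Wilson 95% intervals, 1 line per list (y); red and blue mark lists with a larger or smaller share at an adjusted p below 0.05 by Fisher's exact test, grey the others, and the dashed line all protein-coding genes (10.9%). Cytosolic ribosomal proteins stood highest at 67.9%, and chemoreceptors were at 0.841%.

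Genes of small structural RNAs were marked by summits far more often than chance positions gave. They were examined because such genes can be sites of strong signal in chromatin immunoprecipitation. The possible control experiment was not analysed, so whether signal at them depends on the tagged protein was not tested. Of 612 annotated tRNA genes, 306 (50%) had a summit within 500 bp, against a mean of 3.33% after circular shifts, a ratio of 15.02. These genes were covered by 263 distinct summits, of which 62 also lay in a protein-coding promoter window. The summits lay at the start of the tRNA genes, with a median of 20 bp from the nearest tRNA start (interquartile range -1 to 43 bp). Genes of snRNAs, the RNA parts of the spliceosome and spliced leaders, had a summit in 51 of 129 cases (39.5% against 3.24%), and 22 of their 54 distinct summits also lay in such a promoter window. Genes of snoRNAs, which guide RNA modification, had one in 102 of 346 cases (29.5% against 3.58%), with 48 of their 108 distinct summits in such a window.

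Among the other classes, 39 of 261 miRNA genes (14.9% against 3.44%), 809 of 7764 further ncRNA genes (10.4% against 3.52%) and 22 of 194 lincRNA genes (11.3% against 6.54%) had a summit. Genes of piRNAs, the germline small RNAs that pair with Argonaute proteins, had fewer than after shifts, 68 of 15363 (0.443% against 2.83%). Of 20 rRNA genes 0 had a summit, against 4.17% after shifts (adjusted permutation p = 1). The deposited set leaves out 5 ranked peaks over a cluster with 6 rRNA genes, given below, so the test cannot decide for rRNA genes. For tRNA, snRNA, snoRNA, miRNA, piRNA and ncRNA genes the two-sided permutation p was 0.002, the smallest that 1000 shifts can give, and 0.00266 after adjustment over 8 classes. For lincRNA genes the adjusted permutation p was 0.0206. The lincRNA call ended with a distance of 200 bp (adjusted permutation p = 0.329).

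**Figure D4:**
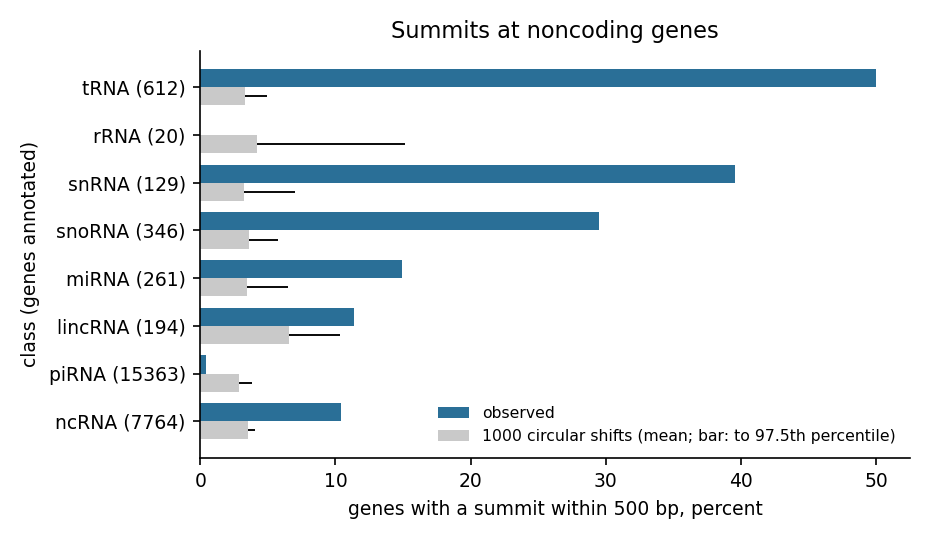
Percent of the genes of each noncoding class (y, with the number annotated) that have a summit within 500 bp (x), observed (blue) and as the mean of 1000 circular shifts (grey, with a line to the upper end of their central 95%). Genes of tRNAs reached 50%, snRNAs 39.5% and snoRNAs 29.5%, while piRNA genes lay below the shifts at 0.443%.

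Summit sequences were richer in G and C than their flanks, and words of repeated A and T were depleted. Within 50 bp of the summit the GC content was 47.5%, against 37.5% in windows of the same size centred 200 bp to 1 side. Of 2080 6-mers, each counted with its reverse complement, 703 occurred more often at summits and 488 less often (exact sign test, adjusted p below 0.05). Of the 10 with the smallest p, 8 were poor in G and C and less frequent at summits. AAAAAT was in 24.1% of summit windows and 44.5% of control windows (exact sign test, adjusted p = 4.2e-70), AAAATT in 20.4% and 38.4%, TAAAAA in 12.1% and 28.4%, and AAAATA in 13.98% and 29.8%. TTAAAA (9.42% and 23.7%), AAATTA (9.09% and 22.2%), AAAAAA (21.1% and 37.3%) and TTGAAA (12.2% and 25.8%) were depleted too, the last with an adjusted p of 1.3e-43. The other 2 were more frequent: ACGCAG was in 12.7% of summit windows and 2.80% of control windows (exact sign test, adjusted p = 9.5e-50), and ACGCGC in 10.03% and 1.67% (adjusted p = 1.9e-47). Among the words chosen after their values were seen, GAGAGA was in 20.4% and 8.81%, and GCGCGC in 8.08% and 1.43%.

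**Figure D5:**
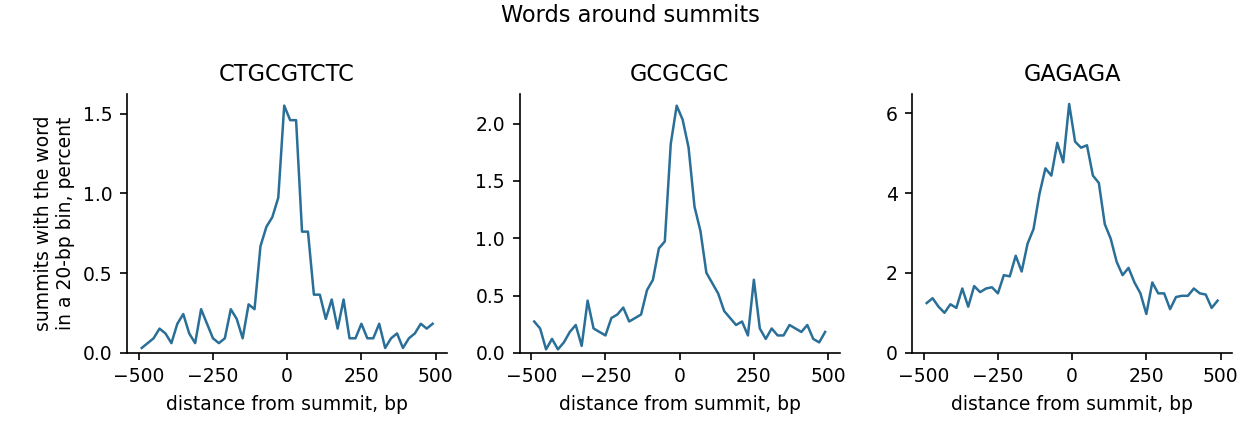
Percent of the 3291 summits with the named word in each 20-bp bin (y) by distance from the summit in bp (x), for CTGCGTCTC, GCGCGC and GAGAGA, each with its reverse complement; the 3 words were chosen after their values were seen. Each curve has its highest values near the summit, and within 50 bp GAGAGA was in 20.4% of windows and GCGCGC in 8.08%.

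The tagged gene itself carried no peak. The gene dxbp-1 (WBGene00013128) lies on the minus strand of chromosome I at 11034059-11038827, and 0 peaks of any thresholded or ranked set fell in it or within 2 kb. Within 10 kb the thresholded sets still held 0 peaks, and the ranked lists held 5 to 8, with a highest signal of 128. The gene lay in a gap of the ranked conservative list that ran from 11026734 to 11056533 (29800 bp). The median gap of that list was 498 bp, and 604 of 32749 gaps were at least as long. In the ranked lists of replicates 1 and 2 the gap was 29406 bp and 24605 bp. Long gaps cover more bases than their number shows, so these counts do not make the position of the gene unusual.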

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

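The comparison of ranked and thresholded lists in this part was chosen after the results were seen. In data outside the comparisons above, 35 ranked peaks met the IDR of at most 0.01 between the samples and yet are left out of the deposited conservative set. They were singled out because they carry signal that the report does not use. The strongest group, 13 peaks at V:7915789-7924751 around the ncRNA gene Y97E10B.12, reached a signal of 1534, a height met by 22 peaks of the conservative set. At V:17122803-17129699, 5 peaks reached 879.5 over a cluster with 6 rRNA genes and 5 spliced leader genes, among them sls-1.1. At V:5283889-5285223, 3 peaks reached 667 with no annotated gene. So the 0 of 20 rRNA genes with a summit is a value of the deposited set, and not of the ranked list. No explanation was tested.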

How the results depend on the processing

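Of 96 checks of the main values and counts under other settings, 90 kept their direction and their side of the threshold or, for counts, stayed within 1.5 times the main count, among them every check of the promoter share, the summit distance, the autosome centres and the numbers of lists with more bound genes and of noncoding classes. That number of classes was 6, and 5 within 200 bp, where lincRNAs lost the call. Leaving out either replicate, the promoter share ranged from 54.9% to 57.0%, the median distance from -172 to -171 bp, the X odds ratio from 0.816 to 0.832, the odds ratio of autosome centres from 1.27 to 1.56, the number of lists with more bound genes from 14 to 15 and the 6-mers more frequent at summits from 597 to 723. The exceptions follow, and the cause was not tested for any of them. Spearman's rho between replicates was 0.812 with an overlap of 50% of both peaks and 0.586 over all ranked pairs. The X odds ratio lost its call with the larger set, at 0.946. The number of lists with fewer bound genes, 5, became 8 without replicate 1, 8 without replicate 2 and 8 with xxx-n names alone. Apart from these 96, among the checks of single lists counted below, the odds ratio of cuticle collagens reversed to 1.12 with nearest-start assignment.

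For single lists, classes and 6-mers with a call, 389 checks kept it, 28 lost it and 1 reversed, and for those without a call, 143 stayed without and 21 gained one. Of the lists with more bound genes, 12 kept the call in all 12 alternatives, and of those with fewer, 3 did. The adjusted p ranged from 8.9e-05 to 0.221 for mitochondrial ribosomal proteins, 0.00845 to 0.546 for aminoacyl-tRNA synthetases, 0.000652 to 0.363 for small RNA pathways, 0.00157 to 0.109 for RNA polymerase II transcription, 2.8e-05 to 0.757 for collagens and 7.0e-07 to 0.168 for lectins. The planned threshold of IDR 0.01 equals the one the authors used, so it gave no other value. No read depth is known, so what depth limits could not be examined.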

Other observations

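The test of weak signal at histone promoters, the test of the word CTGCGTCTC on chromosomes left out, the test of the X recruitment word as the whole of the X difference, the choice of CTGCGTCTC itself, and the counts of spliced leader and other small RNA genes were chosen after the results were seen. Spliced leader RNAs are joined to the front of worm messages. Of the 18 annotated sls-2 genes, which serve genes inside operons, 13 had a summit within 500 bp, and of 12 sls-1 genes 0 did. The 0 is a value of the deposited set, since 5 peaks left out of it lay over 5 sls genes, sls-1.1 and sls-1.10 among them. Signal at sls-2.1 (II:5844865-5844974) was 1493 in the conservative set, with 844 in replicate 1 and 655 in replicate 2. At sls-2.4 (I:4172206-4172315) it was 1043, and at sls-2.8 (III:12250465-12250575) 797. The snRNA gene sup-6 reached 1275, and the snoRNA genes F59C6.15 and ZK994.7 reached 1374 and 1275.

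Summits near tRNA, snRNA or snoRNA genes made up 422 of all summits (12.8%), with a median signal of 311 against 248 for the others. Of the 577 intergenic summits 40 lay near such genes, and of the 24 intergenic summits among the 100 strongest peaks 0 did. Of the named protein-coding genes, 8 had a summit within 500 bp of such a gene: H41C03.3, eif-2Bgamma, snr-4, col-185, clec-126, clec-57, srz-97 and fbxa-83.

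Larger shares of bound genes in 16 lists were weighed against 3 technical explanations, and no biological explanation was tested, since there is 1 group. Transcription of the genes was not measured here and the possible control was not analysed, so neither was weighed. GC content of promoters is argued against as the whole cause, because 15 of 16 lists kept an adjusted p below 0.05 in a logistic model with GC content and window length. The small RNA list lost its call, as its odds ratio went from 2.51 to 1.83 (95% interval 0.791 to 4.21, which now includes 1), and the histone odds ratio went from 4.11 to 1.82. Neighbouring genes and shared summits are argued against for 12 of 16 lists, which kept an adjusted p below 0.05 under circular shifts. Weak signal at promoters with no summit may contribute for some lists, as weak ranked peaks (IDR of at least 0.5) had a median odds ratio of 2.15 (95% interval 1.40 to 3.01). Of the 16 lists 13 were above 1, and 4 of these passed the threshold. Histones did not show it, at 0.263 (0.0997 to 0.694), where 4 of 48 genes with no summit had a weak peak. They were singled out afterwards as the lowest of the 16, so this cannot exclude it for them. The respiratory chain and cytosolic chaperones had 0.809 and 0.869.

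CTGCGTCTC, which overlaps ACGCAG on the other strand, was in 191 of 3291 summit windows (5.80%) and 27 control windows (0.820%), and no biological explanation was tested. Sequence common to all promoters, bound and unbound alike, is argued against. The word was in 6.81% of promoter summits and 0.714% of windows at the same distances from unbound genes. The odds ratio was 9.83 (95% interval 5.58 to 17.3, Fisher's exact test, p = 1.2e-24). With unbound genes as the comparison, the test cannot decide on a sequence common only to the kinds of promoters that were bound. Because the word was picked for its excess at these same summits, that odds ratio and p can overstate the difference. Summit windows held 47.5% GC and promoters of unbound genes a median of 34.7%, which Fisher's exact test does not adjust for. The mean effect of base and CG composition is argued against as the whole cause, by the test chosen after the results were seen. With each of 6 chromosomes left out in turn, the word had the largest excess of summit over control windows among all 9-mers on the others each time. Over those left out, which together are all summits, its ratio of summit to control windows was 6.96 (0.5 added, 95% interval 4.67 to 10.4). The pooled ratio of words with the same bases and CG steps was 2.31. By the test set beforehand, base composition stays open. In it, a ratio at or below the 95th percentile of single rearranged words goes with composition, and 6.96 lay below that percentile of 9. The 121 words with ratios as high had a median of 0 control windows, so that percentile rests on small counts. The word may mark a binding preference of the protein or of a partner, a hypothesis these tests leave open.

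The word was in 6.81% of promoter summits, 6.41% of other intergenic summits and 0.380% of summits near tRNA genes (1 of 263). It was in 3.16%, 4.62%, 8.03% and 7.41% of summits from the weakest to the strongest of 4 groups by signal (Fisher's exact test of strongest against weakest, p = 0.000151). Of 4419 genomic occurrences, 318 (7.20%) lay within 100 bp of a summit. In no list with more bound genes did its share differ from other promoter summits after adjustment, with 3 of 11 summits at cytosolic chaperone genes the highest share (adjusted p = 0.544 by Fisher's exact test).

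On X 44.4% of 604 summits lay in promoters, against 57.8% of 2687 on the autosomes (Fisher's exact test, odds ratio 0.584, p = 2.7e-09). Fewer promoter bases on X may be the reason and stay open: the share over that after shifts was 2.03 on X, within the autosomal range of 1.85 to 2.51. GCGCAGGG, taken here as a word of X recruitment by the dosage compensation machinery, was in 11 of 336 X summits outside promoters and 3 of 1135 autosomal ones (odds ratio 11.4, 95% interval 3.43 to 38.1, Fisher's exact test, p = 1.4e-05), against 2 and 1 of their control windows (odds ratio 5.65, 0.744 to 42.95), so such sites could add to the X summits outside promoters. As the whole of the difference that word is argued against by its rarity, since only 19 summits hold it. Without them 44.9% of X summits and 57.8% of autosomal ones lay in promoters. The odds ratio was then 0.596 (0.498 to 0.713, Fisher's exact test, p = 1.7e-08), and so few summits could move it little. No biological explanation beyond this word was tested. Summits near tRNA genes were not weighed either. Many tRNA genes with a summit lay on X, and over all chromosomes 62 of their 263 distinct summits were in promoter windows.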
